A study of Mus musculus with 8 samples.

How the data were processed

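Mouse testis cells enriched for spermatocytes, round spermatids and condensing spermatids, from WT and H2A.L.2-less animals, were analysed by sequencing of MNase-protected DNA. The 8 libraries comprised 1 per stage and genotype, and at the condensing stage 1 per genotype for each of the 2 fragment classes, which were separated by electrophoresis. Samples were grouped by stage, genotype and fragment class from the sample titles, with 1 library in each group.

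Bowtie2 2.2.9, deepTools 2.2.4 and the mm9 build are named in the submitters' processing notes. Each sample was sequenced in 3 runs that were merged after alignment, with 207000000 to 753000000 reads per sample, per the series description. The reads of single libraries, the version and thresholds of the position caller and any filter on duplicate or multiply aligned reads were not given in the sources used here. Per the file headers, each deposited position has a start, an end, a summit, a summit value and a fuzziness score. The deposited summit value is a coverage signal, a whole multiple of 4 in each list, with no normalization to depth that could be seen in the values. The fuzziness score is the authors' own measure of how widely fragments scatter around a position. All deposited positions were 140 bp wide, no summits of a list were closer than 100 bp, and between 94.9% and 98.8% of summits lay on a 10 bp grid, so distances are resolved to about 10 bp.

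Because summit values carry no common scale, levels were used only relative to the median or the autosomes of the same library. The first percentile of the summit values served as a measure of the calling floor, which was 272 in the WT and 96 in the H2A.L.2-less small-structure list. A weaker position can be missing from a list because coverage there was below the floor, so numbers of positions depend on depth as well as on chromatin.

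Positions on chromosomes 1 to 19 and X were used except where the Y chromosome or mitochondrial DNA is named. A summit was matched when the other list had a summit within 40 bp. Chance was the matched share after moving one list by 5000 bp. Shares have 95% Wilson intervals, whose half-width was at most 0.0466 percentage points. In all, 15 pairs of lists were matched and 10 pairs were correlated across windows. Neighbouring summits up to 1000 bp apart gave the spacing. Distance curves counted pairs of summits in 10 bp bins, divided by the mean from 800 to 1000 bp. Regularity was the highest value from 330 to 450 bp over the lowest from 230 to 330 bp, after smoothing over 5 bins. The repeat length was the slope of a least-squares line of peak position on peak number over the first 4 peaks. It was read only where the ratio exceeded 1.1.

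Windows of 1 Mb with at least 500 positions in both lists were compared by their mean summit value over the library median and by their number of positions. The named windows are the 3 highest and 3 lowest log2 ratios of the mean summit value per comparison, on chromosomes 1 to 19 and X. This rule, the comparisons and their main settings were fixed before the data were examined, as the fallback for the case that no mm9 gene annotation was used. Gene names could not be placed, because the annotation at hand was of another build. Profiles around transcription start sites and promoter values of gene lists, 2 planned results, were therefore not run.

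Several measures were chosen after the data were seen. These are the distance curves within a library with their peak and trough limits, the matched shares by height of the summit, the comparison of small structures with earlier nucleosomes and its alternatives, the windows chosen by position number, and the use of equal numbers of positions for the X density, regularity and window counts. With equal numbers, the 3779744 highest positions of each list were kept, the length of the shortest list. Where summit values tied at the cut, positions were kept in order of chromosome and coordinate, with the X last. Tied X positions were therefore dropped before tied autosomal ones. Alternatives fixed beforehand were matching within 20 or 73 bp, positions at or above the library's median or lower quartile of summit value, gaps of any length, removal of the highest 0.1% of positions, windows of 100 kb, and other measures of a chromosome's level.

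No test across libraries was made, since groups had 1 library, and positions, windows and chromosomes are not replicates. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. The matching and distance code was tested on simulated data: of 8000 simulated positions 59.8% were made to match and 59.8% were recovered, and a simulated repeat of 190 bp was recovered as 190 bp.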

Results

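Chromatin of mouse male germ cells was cut with micrococcal nuclease (MNase), an enzyme that digests DNA not protected by protein, and the protected fragments were sequenced. Germ cells were enriched at 3 stages: spermatocytes, which are in meiosis, round spermatids, the haploid cells that follow, and condensing spermatids, in which histones are replaced by transition proteins and then protamines. At each stage there was 1 library from wild-type (WT) animals and 1 from animals lacking H2A.L.2, a testis-specific histone variant. The condensing stage was further divided by fragment size into nucleosome-sized fragments of about 130 to 170 bp and small structures of about 40 to 80 bp, giving 8 libraries in all. The values are the positions of protected fragments as the authors called them on the mm9 build, each with the height of the coverage at its summit (summit value) and a fuzziness score.

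The lists held 5306949 positions on chromosomes 1 to 19 and X in WT spermatocytes and 4853610 in H2A.L.2-less spermatocytes. Round spermatids gave 5385833 and 4747226 positions, and condensing nucleosomes gave 3779744 and 3885201. The small-structure lists held 5371290 positions in WT and 4114547 in H2A.L.2-less cells. Between 207000000 and 753000000 reads were sequenced per sample according to the series description, but the depth of each library is unknown. The lowest summit values (first percentile) lay between 160 and 176 in the 6 nucleosome lists, and at 272 in the WT and 96 in the H2A.L.2-less small-structure list. Every group had 1 library, so no difference between libraries has a replicate check. The intervals given cover counting error only, and spreads over the 19 autosomes describe variation along the genome, not between animals.

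The first question was how regularly nucleosomes were spaced at each stage. In spermatocytes and round spermatids of both genotypes, summits recurred at a regular distance, and in condensing nucleosomes this repeat was nearly gone. A fragment size range was given for the condensing libraries only. Differences of the condensing from the earlier stages in regularity, fuzziness and matched summits thus cannot be told apart from fragment selection. The repeat length was 187 bp in WT and 190 bp in H2A.L.2-less cells, at both earlier stages, on a 10 bp grid, and 190 bp in all 4 lists with equal numbers of positions. The second peak of the distance curve stood 1.69 ± 0.0242 times above the trough before it in WT spermatocytes (SD over 19 autosomes) and 1.83 ± 0.0278 times in WT round spermatids. In condensing nucleosomes the ratio was 1.02 ± 0.00958 in WT and 1.02 ± 0.00638 in H2A.L.2-less cells, and no repeat length could be read. For small structures the ratios were 1.02 in WT and 1.0 in H2A.L.2-less cells. The peak and trough limits were set for a repeat near 190 bp, so the ratio does not show whether the condensing lists have a shorter one.

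H2A.L.2-less spermatocytes and round spermatids had the more regular summits, with ratios of 1.89 ± 0.0240 and 2.17 ± 0.0490. The order of genotypes was the same with equal numbers of positions per list, where the spermatocyte ratios were 1.92 in WT and 2.08 in H2A.L.2-less cells and the round spermatid ratios 2.14 and 2.38. The most frequent distance between neighbouring summits was 180 bp in the 4 lists of the earlier stages, 130 bp in both condensing nucleosome lists and 140 bp in both small-structure lists. Since the lists hold no summits closer than 100 bp and each position is 140 bp wide, the shortest distances were set by the calling. The median distance was 250 bp in WT and 260 bp in H2A.L.2-less spermatocytes, 240 and 290 bp in round spermatids, 310 and 300 bp in condensing nucleosomes, and 210 and 230 bp in small structures. The SD over autosomes was between 7.08 and 11.8 bp in the 8 lists, and the genotype differences in round spermatids and small structures were larger than the highest of these. These pairs also differed most in list length. Spacing was not computed with equal numbers, so the differences cannot be told apart from list length.

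**Figure D1:**
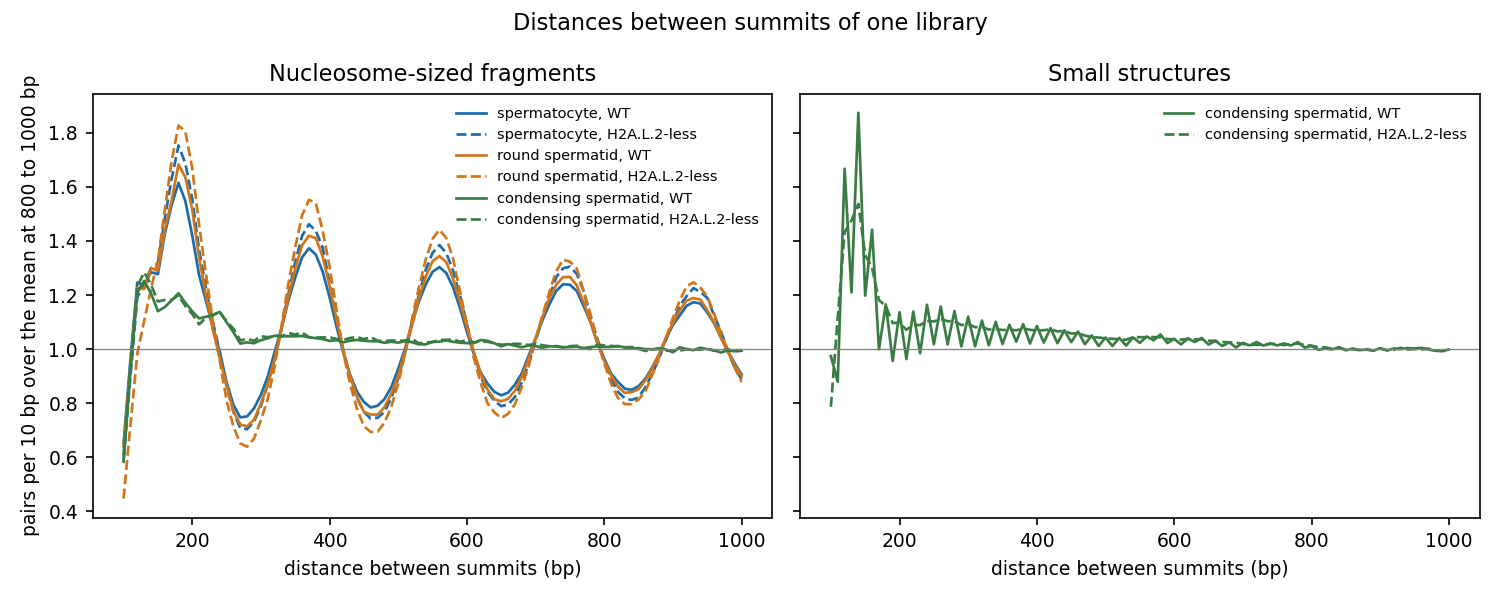
Number of summit pairs per 10 bp of distance within each library, over the mean at 800 to 1000 bp, against the distance in bp, with nucleosome-sized fragments on the left and small structures on the right, solid lines for WT and dashed lines for H2A.L.2-less cells. The curves of spermatocytes and round spermatids rise at 180 bp to between 1.61 and 1.83 and again at 370 bp to between 1.37 and 1.55, while the curves of condensing nucleosomes stand at 1.04 at 370 bp.

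The fuzziness score, the spread the authors' caller gave each position, differed little between nucleosome lists. Its median was 53.3 in WT and 53.1 in H2A.L.2-less spermatocytes, 53.2 and 52.7 in round spermatids, and 54.2 and 54.3 in condensing nucleosomes. Autosomal SDs were between 0.111 and 0.251, so round spermatid positions of H2A.L.2-less cells were less fuzzy than those of WT by more than that spread, and condensing nucleosomes of both genotypes were fuzzier than those of the earlier stages. Among small structures the median was 52.5 ± 0.452 in WT and 50.2 ± 0.610 in H2A.L.2-less cells.

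The comparison of genotypes asked how many WT positions had a counterpart in the H2A.L.2-less list. With 1 library per group, missing counterparts cannot be told apart from differences between libraries. Within 40 bp, 51.0% of WT spermatocyte summits had a summit in the H2A.L.2-less list of the same stage, against 43.4% in round spermatids and 31.0% in condensing nucleosomes. For small structures 57.8% of WT summits were matched, the highest of the 4 shares. Relative to chance, spermatocytes were slightly above small structures within 40 bp, but below them within 20 bp. Chance, measured after moving one list by 5 kb, gave 19.4%, 18.3%, 16.7% and 22.2% in the same order, so the matched share was 2.63, 2.37, 1.86 and 2.60 times chance. The autosomal SDs were 0.588, 0.887, 1.25 and 2.12 percentage points, and the 95% Wilson half-width was at most 0.0466 points.

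Matched shares rose with the height of the summit. Among the 10% of WT summits with the lowest values, between 23.5% and 33.9% were matched in the 4 comparisons. In the highest 10%, 76.0% were matched in spermatocytes, 67.8% in round spermatids, 50.4% in condensing nucleosomes and 84.3% in small structures. The lists differ in length, which sets how often a match is possible. Of the H2A.L.2-less small-structure summits, in the shorter list, 75.4% had a WT summit within 40 bp. With equal numbers of positions the 4 shares were 49.0%, 41.1%, 30.3% and 66.1%.

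**Figure D2:**
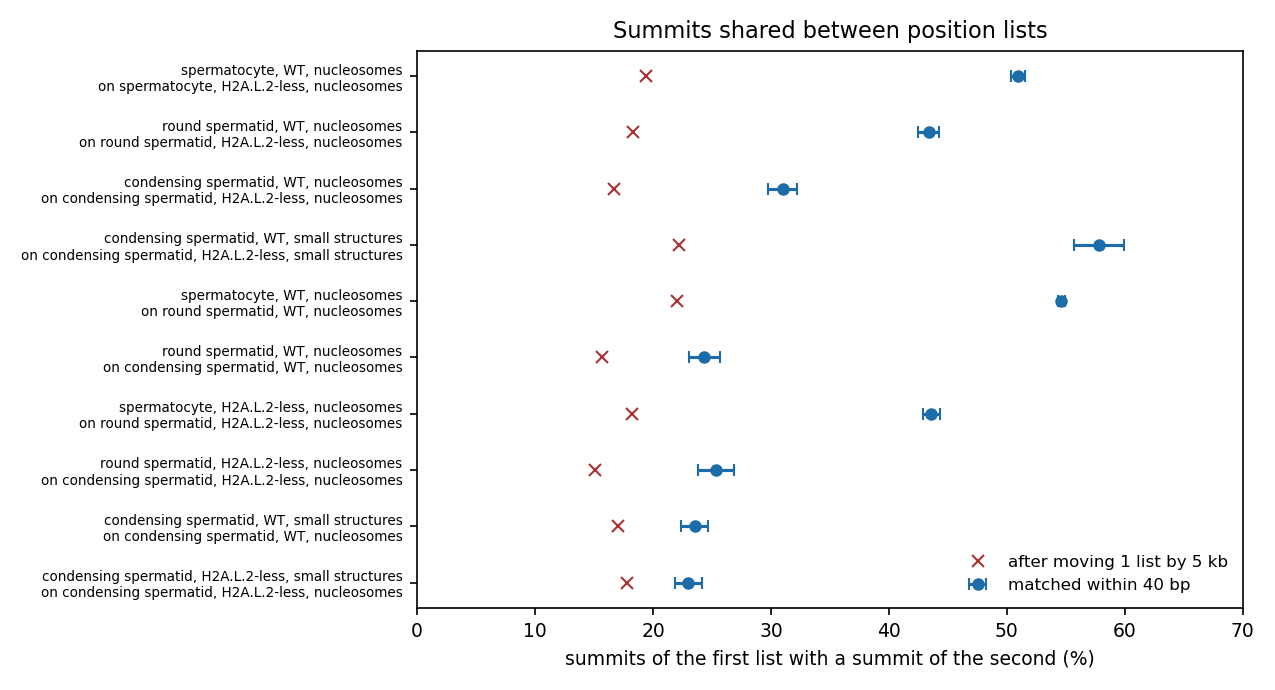
Percentage of the summits of the first list that had a summit of the second list within 40 bp, with bars for the SD over 19 autosomes, and crosses for the percentage after moving one list by 5 kb. WT spermatocyte and round spermatid summits were matched at 54.6% and small structures of both genotypes at 57.8%, while the pairs with condensing nucleosomes lie between 23.0% and 31.0%.

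The stages were then compared within each genotype. In WT, 54.6% of spermatocyte summits were matched in round spermatids (SD 0.297 points, chance 22.0%), and 24.4% of round spermatid summits were matched in condensing nucleosomes (SD 1.35 points, chance 15.7%). In H2A.L.2-less cells the same steps gave 43.6% (SD 0.739 points, chance 18.2%) and 25.3% (SD 1.52 points, chance 15.1%). The step from spermatocyte to round spermatid thus matched 2.48 times chance in WT and 2.39 times chance in H2A.L.2-less cells, and the step to condensing nucleosomes 1.55 and 1.67 times. Among the highest 10% of WT round spermatid summits 36.1% were matched in condensing nucleosomes, and among the lowest 10% the share was 18.6%.

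In condensing spermatids, small structures were set against the nucleosomes of the same cells. Small-structure summits were found at nucleosome summits somewhat more often than chance gives, and were depleted about 100 bp away. Of the WT small-structure summits, 23.5% lay within 40 bp of a WT nucleosome summit (SD 1.16 points, chance 17.0%), and of the H2A.L.2-less ones 23.0% (SD 1.13 points, chance 17.8%). The density of WT small-structure summits was 1.52 times the background at the nucleosome summit, 0.728 times at 100 bp and 1.25 times at 190 bp. In H2A.L.2-less cells the values were 1.42 at the summit, 0.777 at 100 bp and 1.21 at 190 bp.

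Small structures of condensing spermatids were also set against the nucleosomes of the stages before, a comparison added after the data were seen. In WT, 42.0% of small-structure summits lay within 40 bp of a round spermatid nucleosome summit (SD 0.490 points, chance 24.2%), 1.74 times chance, against 1.38 times chance for condensing nucleosomes. In H2A.L.2-less cells the share was 24.3% (SD 0.529 points, chance 18.6%), 1.31 times chance against 1.29 for condensing nucleosomes, so no difference of the WT size was seen there, and its sign turned in other settings (-0.0200 within 20 bp and -0.133 for positions at or above the median summit value). WT small structures set against the H2A.L.2-less round spermatid list gave 25.97%, or 1.39 times chance. On spermatocyte nucleosomes, the shares were 38.3% in WT and 31.1% in H2A.L.2-less cells, 1.64 and 1.49 times chance. Around round spermatid summits the small-structure density was 1.12 in WT and 1.06 in H2A.L.2-less cells at 180 bp. At that distance round spermatid summits themselves were 1.68 and 1.83 times the background. The density was 1.16 in WT and 1.14 in H2A.L.2-less cells at 290 bp. It fell to 0.942 and 0.931 at 370 bp, where round spermatid summits themselves were 1.42 and 1.55 times the background.

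**Figure D3:**
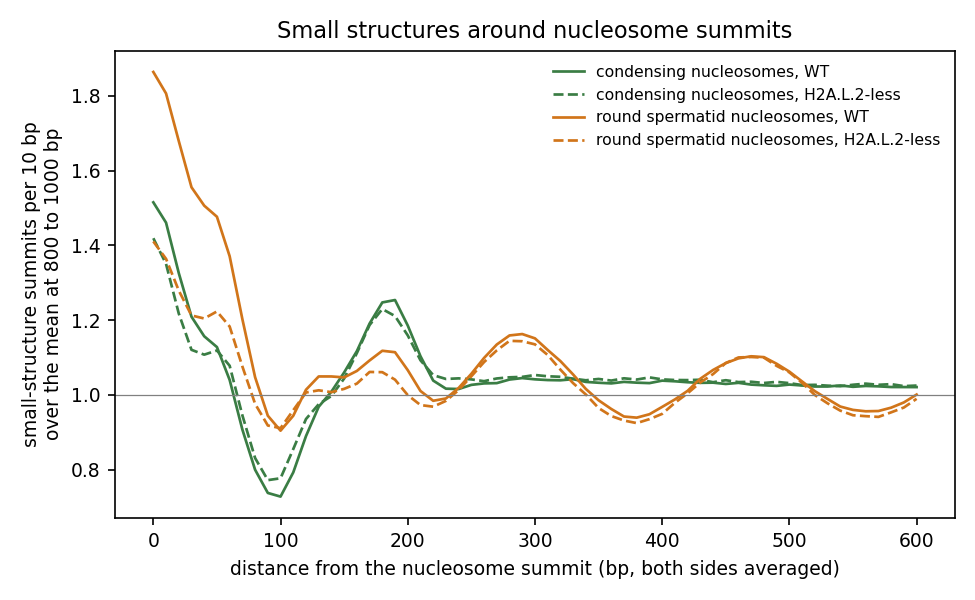
Number of small-structure summits of condensing spermatids per 10 bp over the mean at 800 to 1000 bp, against the distance in bp from a nucleosome summit of condensing (green) or round (orange) spermatids, in WT (solid) and H2A.L.2-less cells (dashed). At the summit the density is 1.86 for round and 1.52 for condensing nucleosomes in WT, and 1.41 and 1.42 in H2A.L.2-less cells.

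Along the chromosomes, the numbers of positions per 1 Mb window were more closely correlated between genotypes in spermatocytes, condensing nucleosomes and small structures than in round spermatids. Across windows of the autosomes, Pearson's r between genotypes was 0.977 in spermatocytes, 0.992 in condensing nucleosomes and 0.992 in small structures, but 0.789 in round spermatids, where r within single autosomes ran from 0.579 to 0.899. WT spermatocytes and WT round spermatids correlated at 0.987, and H2A.L.2-less spermatocytes and round spermatids at 0.886. Windows are not independent replicates, and no test was made.

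Round spermatid windows rich in WT small structures held fewer positions in H2A.L.2-less cells. In the 595 windows with the most WT small structures, the median log2 ratio of position numbers (H2A.L.2-less over WT) was -0.51, and in the 595 windows with the fewest it was 0.28. Over the whole round spermatid lists the log2 ratio was -0.18, and window ratios were not corrected for it. The lowest ratio was on chromosome 10 from 80000001 to 81000000, with 1400 positions in H2A.L.2-less and 3190 in WT round spermatids (log2 ratio -1.19), while the same window held 2579 and 2778 condensing nucleosome positions. The highest was on chromosome 7 from 33000001 to 34000000, with 2230 positions against 964 (log2 ratio 1.21), and with 1631 against 596 in spermatocytes. These windows were chosen after their values were seen.

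Mean summit values per 1 Mb window correlated at r of 0.991 to 0.9996 in all 10 pairs of libraries. Without the highest 0.1% of positions, r was between 0.873 and 0.9875 in 8 pairs, and it fell to 0.413 in WT and 0.389 in H2A.L.2-less cells between small structures and nucleosomes. The highest position of each list lay on chromosome 2 between 98507151 and 98507311, and its summit value was between 46542 and 182427 times the library median. The 100 highest positions held between 7.22% and 14.8% of the summed values in the nucleosome lists and 3.0% and 4.46% in the small-structure lists. By ranks, the correlation between genotypes was 0.714 in spermatocytes, 0.618 in round spermatids, 0.942 in condensing nucleosomes and 0.973 in small structures. Between stages it was 0.655 from WT spermatocytes to round spermatids and 0.382 from there to condensing nucleosomes, against 0.660 and 0.0485 in H2A.L.2-less cells. Without the highest 0.1% of positions, the second step gave 0.274 in WT and -0.129 in H2A.L.2-less cells, a change of sign. Small structures and nucleosomes of condensing spermatids had rank correlations of 0.713 in WT and 0.677 in H2A.L.2-less cells, which rose to 0.766 and 0.718 without those positions, while Pearson's r fell.

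Some of the windows named by the preset rule kept their difference between genotypes without the highest 0.1% of positions. On chromosome 14 from 4000001 to 5000000, mean summit values were lower in H2A.L.2-less than in WT spermatocytes by a log2 ratio of -0.37 (-0.30 without those positions), and in round spermatids by -0.34 (-0.27). On chromosome 14 from 7000001 to 8000000 the ratios were -0.35 (-0.29) and -0.33 (-0.26). In condensing nucleosomes, neither of these chromosome 14 windows was among the 3 lowest genotype ratios. From round to condensing spermatids, WT values fell there by log2 ratios of -0.25 (-0.18) and -0.24 (-0.17). Both were among the 3 lowest ratios of that step in WT, but not in H2A.L.2-less cells. In condensing nucleosomes, 3 windows on chromosome 7 were lowest in H2A.L.2-less cells, starting at 9000001, 7000001 and 10000001, with ratios of -0.22, -0.19 and -0.18. Chromosome 13 from 12000001 to 13000000 was higher by 0.24, also without the extreme positions. On chromosome 10 from 80000001 to 81000000, WT small structures were above WT nucleosomes by 0.70 (0.69 without those positions).

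Most of the other named windows lost their difference without the highest 0.1% of positions. Chromosome 12 from 3000001 to 4000000 was highest in H2A.L.2-less round spermatids, by 1.01, and stood at -0.02 without the highest 0.1% of positions. Chromosome 6 from 103000001 to 104000000 was higher in H2A.L.2-less spermatocytes by 0.60 (0.03 without) and round spermatids by 0.81 (0.03 without). For small structures, chromosome 6 from 132000001 to 133000000 was higher in H2A.L.2-less cells by 1.17 (0.14 without), and chromosome 17 from 39000001 to 40000000 by 0.67 (0.08 without). From round to condensing spermatids, chromosome X from 166000001 to 167000000 rose by 0.48 in both genotypes, and by 0.35 in WT and 0.31 in H2A.L.2-less cells without those positions. With all positions kept, between 94.6% and 99.4% of windows lay within 0.1 log2 of the median ratio in the 4 genotype comparisons.

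The X chromosome held few positions at all stages. It is silenced in spermatocytes during meiosis, where males have a single copy of it, and is present in only part of the haploid spermatids. Its copies are thus fewer than those of an autosome at all stages. The densities were not corrected for the number of X copies, and lower coverage leaves more sites below a calling floor. Per Mb, X positions were at 0.371 of the autosomal mean in WT spermatocytes, 0.176 in round spermatids and 0.122 in condensing nucleosomes. In H2A.L.2-less cells the values were 0.277, 0.146 and 0.125. Small structures on the X stood at 0.222 in WT and 0.244 in H2A.L.2-less cells. Single autosomes lay between 0.739 and 1.36 in the 8 lists, so the X was below every autosome in each library. With equal numbers of positions, the order of genotypes turned in round spermatids, with 0.113 in WT and 0.123 in H2A.L.2-less cells, and in condensing nucleosomes, with 0.122 and 0.109. Small structures then stood further apart, at 0.134 in WT and 0.206 in H2A.L.2-less cells. Tied values at the cut were dropped from the X first, and the WT condensing nucleosome list was not cut at all. The order of genotypes with equal numbers thus cannot be told apart from this rule.

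The height of X positions gave another order, but heights cover called positions only. X sites below a list's calling floor are left out of these medians and means. The median summit value on the X was 0.879 of the autosomal median in WT spermatocytes, 0.867 in round spermatids and 1.04 in condensing nucleosomes, and 0.893, 0.941 and 1.04 in H2A.L.2-less cells, with single autosomes between 0.966 and 1.04 in the nucleosome lists. X positions of small structures were at 0.732 in WT and 0.800 in H2A.L.2-less cells, below the autosomal ranges of 0.894 to 1.098 and 0.9 to 1.1. By the mean, the X was at 1.01 to 1.27 of the autosomes in the lists of spermatocytes and round spermatids, so its direction depends on the measure. X summits were regularly spaced in the earlier stages as well, at lower ratios than the autosomes: 1.19 and 1.16 in spermatocytes and 1.28 and 1.39 in round spermatids for WT and H2A.L.2-less cells.

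The Y chromosome held between 1767 and 2704 positions per list. Its median summit value was level with the autosomal median in WT spermatocytes, at 1.07 of it in round spermatids and 1.32 in condensing nucleosomes, and at 1.05, 1.22 and 1.27 in H2A.L.2-less cells. Small structures on the Y stood at 0.935 in WT and 0.950 in H2A.L.2-less cells. Per Mb, the Y was below the autosomes in all 8 lists, at 0.296 to 0.435.

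**Figure D4:**
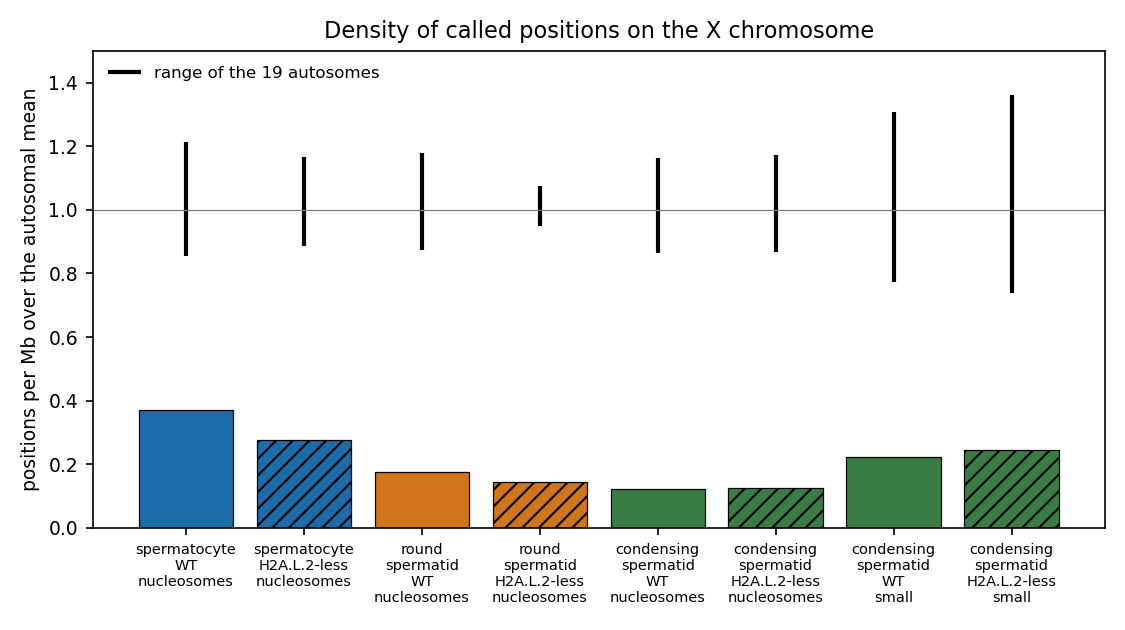
Positions per Mb on the X chromosome over the autosomal mean, as 1 bar per library (plain for WT, hatched for H2A.L.2-less cells), with vertical lines for the range of the 19 autosomes. Bars fall from 0.371 and 0.277 in spermatocytes to 0.122 and 0.125 in condensing nucleosomes, and all 8 lie below the autosomal range.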

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

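The differences between stages listed here were not tested, since each group had 1 library. Of the tests of explanations, those on the density of WT small structures, on condensing nucleosomes as the main site of an H2A.L.2 effect, on the H2A.L.2-less X ratio and floor, and on copy number shared by a genotype were chosen after the result was seen. The limit of 0.1 log2 for single windows and the values without chromosome 7 were also chosen late. Altogether 4 patterns were examined, and 3 are weighed.

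Several contrasts between H2A.L.2-less and WT nucleosomes had one sign in the earlier stages and the other in condensing spermatids, in several cases by no more than the spread over autosomes. The log2 ratio of the number of positions was -0.13 in spermatocytes and -0.18 in round spermatids but 0.0397 in condensing nucleosomes. Median spacing differed by 10 bp, 50 bp and -10 bp in the same order, H2A.L.2-less minus WT, and the autosomal SDs of the spermatocyte and condensing lists were between 9.90 and 11.8 bp. Median fuzziness differed by -0.207, -0.504 and 0.0748, with SDs up to 0.251 in spermatocytes and 0.129 in condensing nucleosomes, so that the round spermatid value alone exceeded its spread. The second peak of the distance curve over its trough differed by 0.201, 0.339 and -0.00432, the last within the autosomal SD of 0.00958. X density over autosomes differed by -0.0944, -0.0301 and 0.00320, but with equal numbers of positions the signs in round spermatids (0.113 in WT, 0.123 in H2A.L.2-less cells) and condensing nucleosomes (0.122 and 0.109) were the opposite. Tied values at that cut were dropped from the X first, so the opposite signs cannot be told apart from this rule. The Y median summit value over autosomes differed by 0.0536, 0.149 and -0.0492.

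Mitochondrial DNA, outside the comparisons of the report, had a median summit value of 5.74 times the library median in H2A.L.2-less condensing nucleosomes and 4.84 times in WT, from 90 and 95 positions. The small-structure lists gave 1.55 in WT and 1.43 in H2A.L.2-less cells, from 59 and 50 positions. In spermatocytes and round spermatids it was between 0.893 and 0.967, from 5 to 21 positions per list.

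The round spermatid lists of both genotypes differed in where positions were called. The number of positions did not account for this, as the correlation of window counts was 0.722 with equal numbers. An effect of H2A.L.2 that is strongest in condensing spermatids could not be judged from window counts. Their correlation of 0.992 between genotypes in condensing nucleosomes is part of the pattern itself. Single summits were matched least in condensing nucleosomes (1.86 times chance, against 2.37 in round spermatids). Without a second library of the same genotype, this does not show where an effect of H2A.L.2 is strongest. A preset test of an axis shared with WT libraries, such as digestion or DNA composition, came out against it: the round ratio correlated at 0.0829 with the ratio of WT condensing to WT spermatocyte counts. A later test gave r = -0.945 with the density of WT small structures, and the round contrast correlated at 0.890 with the genotype contrast of spermatocytes, -0.744 with that of small structures and 0.00471 with that of condensing nucleosomes, so digestion or base composition may still be a source along another axis, and an effect of the genotype also stays open.

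X positions were fewer in round spermatids than in spermatocytes, relative to autosomes, in both genotypes. Equal numbers left the WT ratio at 0.427. The WT round spermatid list was already the longer one (5385833 against 5306949 positions), so this check could not show an effect of list length. The H2A.L.2-less lists gave 0.527, so the pattern was not confined to the WT lists, but this restates the pattern and tests no cause. If X coverage is lower than that of autosomes, a floor closer to the typical coverage could remove X positions. In WT the share of autosomal positions at or above 2 floors was 9.98% in round spermatids and 8.15% in spermatocytes, 1.22 times as high. Neither share matches the X density over autosomes, 0.176 and 0.371 in the same order, so the comparison cannot exclude the floor. In H2A.L.2-less cells the share at or above 2 floors in round spermatids was 0.473 of the spermatocyte value. The floor thus remains a candidate cause there and is not excluded in WT. A difference in X chromatin between the stages stays open as a hypothesis for both genotypes.

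In condensing nucleosomes, 9 of 2151 windows departed from the median genotype ratio by more than 0.1 log2, without the highest positions. DNA copy number of the animals used would move nucleosomes and small structures together, and over these windows the contrasts correlated at 0.853, with 7 of 9 of the same sign. That value rests on 3 windows of chromosome 7 between 7 and 11 Mb, without which r was 0.329 over 6 windows. Copy number shared by all animals of a genotype is argued against, as the cause of all 9 windows, by an r of -0.339 with the spermatocyte contrast, where 2 of 9 windows had the same sign. For these 2, on chromosome 13 from 12 to 14 Mb, it stays open. They lay above the median genotype ratio in all 4 contrasts, but by as little as 0.742 SD of all windows. Their median small-structure summit values, over the library median, were 0.959 and 0.975 in WT. In H2A.L.2-less cells they were no higher, at 0.950 and 0.975. For the chromosome 7 windows, copy number in the animals of the condensing libraries, a difference between cell preparations and an effect of the genotype stay open.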

How the results depend on the processing

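Alternatives with equal numbers of positions for regularity, X density and window counts, and all those for small structures on round against condensing nucleosomes, were chosen after the data were seen, and the others were fixed before. Lists of values run, unless said otherwise, from spermatocytes through round spermatids and condensing nucleosomes to small structures, with WT before H2A.L.2-less cells in each pair. Where no reason follows from the setting itself, the cause was not tested. Windows of 100 kb left Pearson's r of mean summit values at 0.991 or above, but extreme positions hold that measure high. The rank correlation between genotypes fell at 100 kb from 0.942 to 0.742 in condensing nucleosomes, that of small structures with nucleosomes from 0.713 to 0.590 in WT and from 0.677 to 0.508 in H2A.L.2-less cells, and that of WT round spermatids with condensing nucleosomes from 0.382 to 0.262. The per-library depth is unknown, so how far weak positions were missed in each list cannot be stated. Profiles around transcription start sites and promoter values of gene lists were not run, with all their alternatives. The replicate numbers pair no libraries, since each group had 1, and no model of genotype across the 3 stages was fitted.

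Shares matched between genotypes (spermatocyte, round spermatid, condensing nucleosome, small structure) were 35.7%, 30.0%, 19.9% and 47.0% within 20 bp and 64.3%, 55.0%, 44.6% and 65.8% within 73 bp. For positions at or above the median summit value they were 41.9%, 33%, 25.2% and 54.9%, and with equal numbers of positions 49.0%, 41.1%, 30.3% and 66.1%. The order of the 4 shares was the same in each, but relative to chance it was not. Within 20 bp, small structures stood at 3.82 times chance and spermatocytes at 3.33. For the upper values small structures, at 3.23 times chance, lay below round spermatids at 3.40. Between stages (WT spermatocyte to round, WT round to condensing, then the same for H2A.L.2-less cells), shares were 37.7%, 14.99%, 29.5% and 15.5% within 20 bp, 70.1%, 36.9%, 56.8% and 38.2% within 73 bp, 44.8%, 16.8%, 33.6% and 18.9% for the upper values, and 48.6%, 26.4%, 40.0% and 26.02% with equal numbers. With equal numbers, the order of the genotypes at the second step turned in the share but not relative to chance (1.66 times in WT, 1.76 times in H2A.L.2-less cells). Small structures on condensing nucleosomes gave 14.03% in WT and 13.6% in H2A.L.2-less cells within 20 bp, 35.2% and 35.6% within 73 bp, 15.2% and 15.02% for the upper values, and 25.1% and 22.7% with equal numbers. A wider distance admits more matches by construction. The difference between round and condensing nucleosomes in matches of H2A.L.2-less small structures, relative to chance and chosen late with its alternatives, turned to -0.0200 within 20 bp and -0.133 for the upper values.

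Median spacing above the lower quartile of summit values was 290, 300, 260, 340, 340 and 330 bp in the 6 nucleosome lists, and 210 and 230 bp, as before, in small structures. With gaps of any length it was 280, 320, 260, 345, 380, 360, 220 and 250 bp. Median fuzziness at or above the median summit value was 52.6, 52.3, 52.5, 51.8, 53.6, 53.8 and, in WT small structures, 52.9. The highest 0.1% of positions did not move it beyond the spread in any of the 8 lists. Regularity with equal numbers of positions was 1.92, 2.08, 2.14 and 2.38 in the 4 lists of the earlier stages and moved by less than the spread in the 4 condensing lists.

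The level of the X against autosomes changed direction with the measure. Its median and mean leave out sites below the calling floor, so they describe only the X positions that were called. By mean summit value it was 1.01, 1.09, 1.06 and 1.27 in the earlier stages, above the autosomes where the median lay below them, and 1.62, 1.53, 0.925 and 0.913 in the condensing lists. By positions per Mb it was 0.371, 0.277, 0.176, 0.146, 0.122, 0.125, 0.222 and 0.244, so that in condensing nucleosomes it lay below the autosomes where the median lay above the autosomal median. That X median, 1.04 in both genotypes, was above every single autosome in WT (up to 1.02). In H2A.L.2-less cells single autosomes reached the same 1.04. With equal numbers, the density was 0.265, 0.222, 0.113, 0.123, 0.122, 0.109, 0.134 and 0.206, with tied values at the cut dropped from the X first. The Y by mean summit value was 6.16, 7.09, 6.32, 8.02, 8.37, 7.89, 3.60 and 2.87, which turned the direction in both small-structure lists. By positions per Mb it was 0.435, 0.402, 0.296, 0.327, 0.399, 0.382, 0.357 and 0.398, which turned the direction in the other lists except WT spermatocytes, where the median was level with the autosomes.

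Correlations of mean summit values across windows were lower without the highest 0.1% of positions, most of all between small structures and nucleosomes. Between genotypes, r was then 0.922, 0.916 and 0.9875 in the 3 nucleosome stages and 0.987 in small structures, the last within the autosomal spread. Between stages it was 0.936 and 0.873 in WT and 0.954 and 0.9003 in H2A.L.2-less cells, the last within that spread. Between small structures and nucleosomes it was 0.413 in WT and 0.389 in H2A.L.2-less cells. By number of positions, r moved to 0.789 for round spermatids between genotypes, 0.886 for H2A.L.2-less spermatocytes to round spermatids and 0.782 for the step from there to condensing nucleosomes. With equal numbers these 3 were 0.722, 0.811 and 0.713, and condensing nucleosomes between genotypes gave 0.985.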

Other observations

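All values in this part come from comparisons chosen after the data were seen, and nothing here was tested across libraries.

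The preference of small structures for round spermatid nucleosome positions over condensing ones, each relative to chance, differed between genotypes. The difference was 0.353 in WT and 0.0149 in H2A.L.2-less cells, and 0.371 and 0.00372 with equal numbers of positions. In WT it was 0.356 within 20 bp, 0.335 within 73 bp and 0.303 for positions at or above the median summit value. In H2A.L.2-less cells these were -0.0200, 0.0356 and -0.133, so the sign depends on the setting there. The H2A.L.2-less round spermatid list also departs from the other lists in its window counts, and WT small structures matched it at 1.39 times chance, so the values depend on which round spermatid list is used.

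In windows on chromosome 10 from 79000001 to 81000000, the 2 windows with the lowest ratio of H2A.L.2-less to WT round spermatid positions, spermatocytes changed in the same direction, with 1867 and 1839 positions in H2A.L.2-less and 2712 and 2684 in WT cells. Condensing nucleosomes held 2654 and 2579 against 2733 and 2778 there, and small structures 4960 and 4978 against 5320 and 5339. These counts were not scaled to list length. The whole small-structure list was shorter in H2A.L.2-less cells (4114547 against 5371290 positions), by a larger factor than in these windows.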
